A study of Mycolicibacterium smegmatis with 6 samples.

How the data were processed

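Total RNA of 6 samples of Mycolicibacterium smegmatis, 3 with an interrupted ltmA gene and 3 of the wild type, was sequenced. Per the labels' protocols, RNA was taken up in Trizol, a column kit was used with 1 µg of total RNA, and libraries followed standard Illumina steps. Per the submitters' processing notes, reads were processed with Bowtie2, with no version given. The read counter, the annotation release, the strand setting and the handling of reads that match several places are not given in the sources used here.

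The authors deposited a table of FPKM values (reads scaled by gene length and by the total of assigned reads), per the file headers, for 6938 genes in each of the 6 libraries. Of these genes, 6132 carried a locus tag in the table; 675 more were given a tag from the reference gene table by matching both ends and 125 by matching 1 end, and 6 had none. Coordinates are those of the table and match assembly ASM1500v1. Gene lengths were multiples of 3 in 97.5% of genes and hold coding length.

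In every library FPKM multiplied by length was a whole multiple of 1 step for 100% of genes (tolerance 0.01 of a read) and summed to the same total, so the number of reads behind each value could be recovered: 11769971, 11760038 and 15383650 in the knockout and 10665621, 11372948 and 11240975 in the wild type. At a length of 1 kb, 1 read was worth 0.0650 to 0.0938 FPKM. The main test used the FPKM values, since the deposited unit is FPKM; the recovered reads gave depths, the ltmA interval and an alternative. That interval is an exact one for a ratio of counts at 95% and covers counting error only.

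Replicates were compared before averaging. Over genes with at least 20 reads, the chi-square per degree of freedom was 2.21 to 2.49 between knockout libraries and 3.82 to 6.73 between wild-type libraries, so every pair differed by more than sampling noise and all 6 were kept as separate samples. Between groups it was 107 to 145. Ribosomal RNA took at most 0.000106% of assigned reads. The handling of reads that match several places is not given, so this value does not show how well ribosomal RNA was removed.

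Each gene with a mean of at least 1 FPKM (6713 genes; 225 were below) was tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), genotype as the single term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Of the 225 genes below the filter, 115 lie in 2 unbroken runs of neighbours, MSMEG_1002 to MSMEG_1058 and MSMEG_2282 to MSMEG_2339. With the handling of reads that match several places not given, low values there do not show that these genes were silent. Fold changes are on the log2(FPKM + 1) scale. Gene lists were tested with limma's camera at a preset correlation of 0.01, camera with an estimated correlation, and fry, each adjusted over the 34 lists with at least 3 tested members. A list's median was also placed among 10000 random lists of equal size matched on mean expression. The lists, the tests, the groups and most other settings were fixed before the data were examined.

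Genes were named by a rule fixed at the same time: ltmA and the 4 genes on either side; the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap and whose mean reached 10 FPKM in a group; and per list up to 4 members past the threshold with the smallest adjusted p, or the 2 highest if none passed. Genes named outside it are said to be chosen after their values were seen. These include MSMEG_0615, MSMEG_0625 and MSMEG_2196.

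The test was checked on 10 simulated data sets for the comparison of knockout and wild type (6709 to 6716 genes tested), drawn from the mean levels and depths of the real libraries with a dispersion of 0.00743 estimated from the replicates and with 200 genes changed. It recovered 72.1% of genes changed 1.5-fold, 95.4% of those changed 2-fold and 99.1% of those changed 4-fold. On average 6.26% of calls were false, above the nominal 5%. A first version with 1 data set and a dispersion set by hand gave a higher share of false calls and was replaced after that result was seen. A list of 20 raised genes was called in 10 of 10 data sets, and 0 of 300 lists of unchanged genes were called. The simulated genes were drawn independently, with a single dispersion and no shift of weak genes, and the real data had 5397 calls. These rates therefore do not carry over to the real list calls. In the real libraries, groupings that mixed knockout and wild type called 3 to 11 lists.

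Alternatives changed the pseudocount, the filter, the normalization, the trend, the replicate block and the set test, and left out each library in turn. Filters at 50 and 100 FPKM, subtraction of the 25th percentile together with a pseudocount of 10, limma's voom on the recovered reads, case-matched list searches and other settings joined with an estimated correlation were chosen after the data were seen. Figures were drawn with matplotlib 3.10.9.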

Results

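RNA levels were measured by sequencing in Mycolicibacterium smegmatis, a fast-growing soil mycobacterium. A strain with the ltmA gene interrupted by a hygromycin resistance cassette (3 libraries) was compared with a wild-type strain (3 libraries). LtmA is a DNA-binding regulator described as responding to the second messenger cyclic di-GMP and as acting on genes of lipid transport and metabolism. The comparison asks which transcripts differ when ltmA is interrupted. Per the labels, the knockout carried the plasmid pMV261 with no insert named, and the wild type carried pMV261 with a substituted ydeH insert. Strain and insert therefore differ together in every comparison below. The knockout libraries held 11769971, 11760038 and 15383650 assigned reads and the wild-type libraries 10665621, 11372948 and 11240975. Values are FPKM, given as mean ± SD with n = 3 per group. Log2 fold changes are knockout minus wild type on the log2(FPKM + 1) scale, which understates the change of weak genes. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

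The interrupted gene, ltmA (MSMEG_6479, bases 6542615 to 6543184 of the chromosome, assembly ASM1500v1), fell from 26.7 ± 4.09 FPKM in the wild type to 0.576 ± 0.243 in the knockout. The knockout libraries held 2, 5 and 6 ltmA reads and the wild-type libraries 137, 199 and 173. The ratio of wild type to knockout was 45.8, with a 95% interval of 26.5 to 86.6 that covers counting error only. The log2 fold change was -4.14 (SE 0.23, limma adjusted p = 1.0e-09), lower in 3 of 3 knockout libraries. An interrupted gene can still give reads from the parts outside the cassette.

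Around ltmA, 7 of the 8 nearest genes rose in the knockout and 1 fell. MSMEG_6478, a cytochrome P450 gene at bases 6540573 to 6541916, rose from 51.8 ± 2.07 to 5729 ± 16.9 FPKM (111-fold; log2 fold change 6.76, SE 0.03, limma adjusted p = 1.9e-22), the largest rise among the 6713 genes tested. On the same side, MSMEG_6476 (hypothetical protein) rose by 3.13 on the log2 scale and MSMEG_6480 (transcriptional regulatory protein) by 2.06. On the other side, MSMEG_6482 (hypothetical protein) rose by 2.76, MSMEG_6483 (methyltransferase) by 1.72, MSMEG_6484 (glycosyl transferase family) by 1.59 and MSMEG_6481 by 1.01. Between these risers, MSMEG_6477, the methionine sulfoxide reductase A gene that repairs oxidised methionine, fell from 848 ± 8.48 to 179 ± 15.7 FPKM (log2 fold change -2.24, SE 0.05, adjusted p = 5.4e-14). Further out, MSMEG_6475 rose by 1.09, and MSMEG_6488, MSMEG_6489 and MSMEG_6490 fell, with log2 fold changes of -1.22, -1.77 and -1.94. These last 4 genes were named after their values were seen. The annotations of MSMEG_6480 and ltmA overlap from base 6542615 to base 6542638, and the strand setting of the counting is not given in the sources used here. In the list of ltmA and its neighbours (9 genes, MSMEG_6475 to MSMEG_6483), 7 rose and 2 fell, ltmA itself being 1 of the 2. The list passed as higher (camera adjusted p = 3.6e-05, and adjusted p = 0.465 with an estimated correlation), and not among genes at 100 FPKM or more (0.122).

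**Figure D1:**
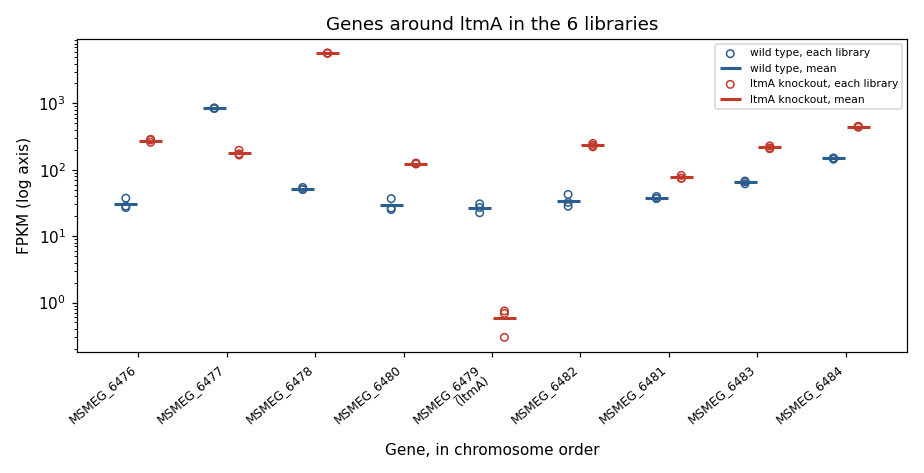
FPKM on a log axis of ltmA and the 4 genes on either side in chromosome order; open circles are the 3 libraries of each group and bars their means. MSMEG_6478 stands at 51.8 FPKM in the wild type and 5729 in the knockout, while ltmA and MSMEG_6477 are lower in the knockout.

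Across the genome, 1259 genes rose in the knockout and 4138 fell, out of 6713 tested (5397 in all, limma with Benjamini-Hochberg adjustment). The direction depended on the level of the gene. Of the 1462 genes with a mean of 1 to 10 FPKM, 4 rose and 1316 fell; of the 2767 genes with a mean of at least 50 FPKM, 1131 rose and 1011 fell. At least 2-fold changes numbered 75 rises and 1996 falls over all levels, and 67 rises and 50 falls among genes at 50 FPKM or more. The median log2 fold change over the tested genes was -0.42.

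Weak genes had more signal in each wild-type library than in any knockout library. The 25th percentile over all genes was 4.72, 4.85 and 5.30 FPKM in the knockout and 13.2, 17.4 and 14.5 in the wild type. Genes at 4 to 8 FPKM in the knockout lay 10.1 FPKM higher in the wild type (median of 728 genes), and those at 64 to 128 FPKM differed by -0.51 (median of 803 genes). The 3 knockout values all lay on one side of the 3 wild-type values for 5457 genes (81.3%; chance gives 10%). The shares of rises and falls moved with the scaling. They were 23.3% and 76.7% in the main test, 49.0% and 51.0% after quantile normalization, and 47.5% and 52.5% after centring each library on its median. Subtracting each library's 25th percentile together with a pseudocount of 10, a setting chosen after the data were seen, gave 61.2% and 38.8%. Every value given below for this subtraction carries both changes. Quantile normalization and centring shifted the median log2 fold change by 0.40 and 0.38.

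**Figure D2:**
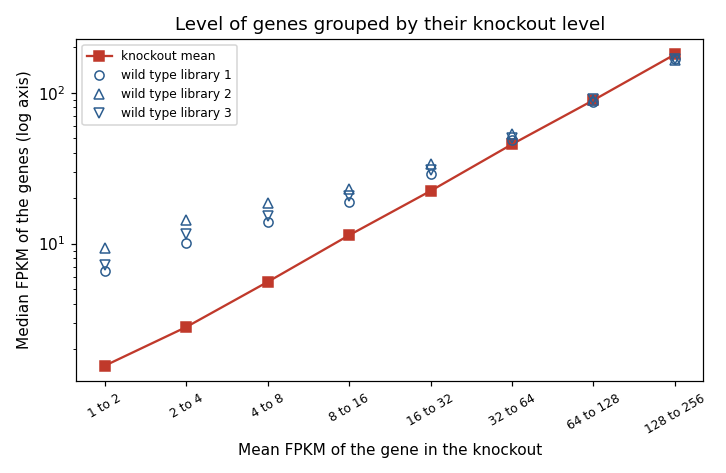
Median FPKM (log axis) of genes grouped by their mean FPKM in the knockout, for the knockout mean (squares) and each wild-type library (open symbols). The wild-type medians lie above the knockout below 32 FPKM, with 15.9 against 5.57 FPKM in the group at 4 to 8, and meet it at 64 to 128.

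Away from the ltmA locus, the largest rises were in MSMEG_5344 (hypothetical protein, 66.5 ± 11.5 to 340 ± 17.0 FPKM, log2 fold change 2.35, SE 0.09) and MSMEG_5236. The latter encodes a dienelactone hydrolase, an enzyme that opens lactone rings, and rose by 2.22 (61.2 ± 4.69 to 289 ± 9.75 FPKM, SE 0.06). MSMEG_1919, a WhiB family transcription factor, rose from 406 ± 38.7 to 1356 ± 27.5 FPKM. MSMEG_0416, MSMEG_1770 and MSMEG_1475, all hypothetical proteins, rose by 1.81, 1.72 and 1.66, and the tRNA gene MSMEG_5757 rose by 1.63. In these genes limma adjusted p ran from 1.7e-13 to 4.6e-07, and each was higher in 3 of 3 knockout libraries.

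The 11 largest falls after ltmA were all in genes at 38.1 FPKM or less in the wild type, the range in which most genes fell. They were led by MSMEG_3096 (27.4 ± 6.25 to 1.93 ± 1.79 FPKM, log2 fold change -3.51, SE 0.41, limma adjusted p = 2.9e-06) and MSMEG_5098 (37.2 ± 13.4 to 2.99 ± 1.34 FPKM, log2 fold change -3.27). The other 9 had log2 fold changes from -3.20 to -2.91. They were the hypothetical protein genes MSMEG_1450, MSMEG_1948, MSMEG_5528, MSMEG_0910, MSMEG_4341, MSMEG_0804, MSMEG_6893 and MSMEG_6549, and the tRNA gene MSMEG_5758. Among genes at 100 FPKM or more in the wild type, a level set after the values were seen, the largest falls were MSMEG_4506 (109 ± 17.6 to 19.9 ± 2.35 FPKM), MSMEG_4508 (113 ± 7.37 to 22.4 ± 3.0 FPKM) and MSMEG_6477. Of the next 9, 7 were ESX-3 genes, described below. The others were MSMEG_1236 (Mpr protein, 171 ± 0.594 to 39.7 ± 5.27 FPKM) and MSMEG_1264 (prophage protein, 174 ± 4.36 to 46.7 ± 4.73 FPKM).

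Gene groups were compared as 35 lists fixed before the data were examined, 34 of them with at least 3 tested members. By camera, which asks whether a list's moderated statistics differ from those of the other genes, 15 lists passed (4 higher and 11 lower in the knockout). These statistics divide a change by its spread, so a list can pass as lower without falling more than other genes. The main ribosomal, bcc-aa3 oxidase, mycolic acid and ATP synthase lists did so. Their mean log2 fold changes lay above the mean of the other genes by 0.35, 0.29, 0.16 and 0.05. With an estimated correlation between genes 0 lists passed, 3 lists had an unadjusted p under 0.05, and the smallest adjusted p was 0.185. Another 10 lists passed under at least 1 other scaling or filter, and 0 of these did so there with an estimated correlation (smallest adjusted p 0.0963). By fry, which tests whether a list's own genes move on balance in a single direction and does not compare them with other genes, 32 lists passed. All 34 passed its mixed test of change in either direction. Counts of members below are those adjusted over all tested genes; adjusted over the list alone they were the same for 29 lists, and both are given for the other 6. For each group, the number of members under 20 FPKM in the wild type is given where it is above 0. Genes at that level were lower in the knockout as a whole. The shift did not end there: of 1257 genes with a mean of 20 to 50 FPKM, 108 rose and 778 fell. A list with few or 0 members under 20 FPKM can therefore still lie within the shift.

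The ESX-3 and ESX-1 genes, which encode type VII secretion systems of mycobacteria, fell together. Of 12 ESX-3 genes, 10 fell and 0 rose. MSMEG_0620 (PE family protein) fell from 814 ± 8.4 to 185 ± 0.499 FPKM (log2 fold change -2.13, SE 0.03), and MSMEG_0622 from 366 ± 9.51 to 91.5 ± 1.37. MSMEG_0621 fell from 417 ± 32 to 91.5 ± 5.68 FPKM and snm from 254 ± 9.32 to 62.0 ± 4.71. MSMEG_0615 (log2 fold change 0.13, adjusted p = 0.233) and MSMEG_0625 (log2 fold change 0.11, adjusted p = 0.312) did not pass. Of 26 ESX-1 genes, 25 fell and 0 rose, with 1 member under 20 FPKM. MSMEG_0065 fell from 1520 ± 27.5 to 747 ± 17.8 FPKM (log2 fold change -1.02, SE 0.03), and MSMEG_0066, the early secretory antigenic target, from 1100 ± 58.7 to 558 ± 13.0. MSMEG_0067 and MSMEG_0068 had log2 fold changes of -0.93 and -1.11. The ESX-3 median was -1.75 (camera adjusted p = 0.00430, and adjusted p = 0.465 with an estimated correlation). The ESX-1 median was -0.84 (camera adjusted p = 3.5e-05, and adjusted p = 0.185 with an estimated correlation), and -0.46 after centring on the median. Among 10000 random lists of equal size matched on mean expression, both medians lay at percentile 0. So did those of the ATP synthase and mycolic acid lists. Of other lists that camera called lower, MCE and YrbE lay at percentile 59.3, nitrogen limitation at 17.0 and the rest at 4.37 or less. Of those called higher, chaperones lay at 36.4, cytochrome bd at 84.4 and the rest at 99.6 or more. The random lists were drawn gene by gene, so they do not carry shared movement within operons.

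**Figure D3:**
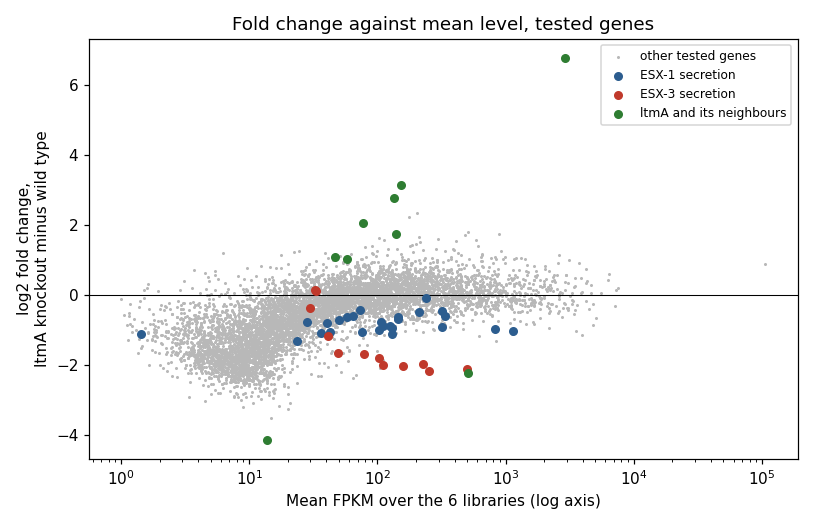
Log2 fold change (knockout minus wild type) against mean FPKM over the 6 libraries (log axis) for the 6713 tested genes, with the ESX-1, ESX-3 and ltmA locus lists coloured. Grey points drop below 0 toward low FPKM, and the ESX-3 genes reach -2.17 at levels where other genes centre near 0.

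Genes for iron acquisition through the siderophores exochelin and mycobactin also fell. Of 21 members, 18 fell and 1 rose, with 2 members under 20 FPKM and a median wild-type level of 27.3 FPKM. The mycobactin synthesis genes MSMEG_4511 and MSMEG_4509 fell from 86.7 ± 0.992 to 18.0 ± 0.944 FPKM and from 66.4 ± 2.74 to 15.3 ± 1.27. MSMEG_4510 fell from 56.6 ± 3.90 to 14.0 ± 0.553 FPKM, and MSMEG_4508 beside them fell by 2.29 on the log2 scale. The list median was -1.40 and lay at percentile 0 among matched lists (camera adjusted p = 0.00907, and adjusted p = 0.567 with an estimated correlation). It was -0.59 after quantile normalization, -0.87 with a pseudocount of 10 alone, and -0.58 with that pseudocount and subtraction of the 25th percentile together. With the 3 members at 50 FPKM or more alone, the list did not pass (camera adjusted p = 0.132, with a median of -2.21).

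In energy metabolism, all 8 ATP synthase genes fell. The subunit gene atpA fell from 509 ± 3.52 to 331 ± 8.48 FPKM, atpD from 687 ± 23.6 to 465 ± 7.12 and atpE from 938 ± 11.5 to 632 ± 30.9, and MSMEG_4939 fell by 0.56 on the log2 scale. ATP synthase as a list had a median of -0.56 (camera adjusted p = 0.00430, and adjusted p = 0.465 with an estimated correlation). After centring on the median it did not pass (adjusted p = 0.363, with a median of -0.18). All 6 genes of the cytochrome bcc-aa3 oxidase, the main terminal oxidase branch, fell. MSMEG_4263 fell from 3025 ± 45.4 to 2108 ± 10.1 FPKM, and MSMEG_4262, MSMEG_4267 and MSMEG_4268 had log2 fold changes of -0.43, -0.31 and -0.23. The bcc-aa3 median was -0.27 (camera adjusted p = 0.0395, and adjusted p = 0.465 with an estimated correlation). After centring on the median, that list, MSMEG_4267 and MSMEG_4268 had the opposite direction, with a list median of 0.11. Its call also ended without the intensity trend (0.234), without a filter (0.0574) and without knockout library 3 (0.0534). The 3 genes listed for cytochrome bd oxidase, an alternative oxidase with high oxygen affinity, rose. MSMEG_3233 rose from 687 ± 12.3 to 940 ± 8.18 FPKM, cydB from 678 ± 9.18 to 842 ± 15.1 and cydD by 0.12 on the log2 scale. The annotation of cydD is a cysteine ABC transporter protein and not an oxidase subunit. Without cydD the list would have fewer than the 3 members that a list test needs. This list passed as higher (camera adjusted p = 0.00622, and adjusted p = 0.465 with an estimated correlation). It did not pass after quantile normalization (0.0845), after centring (0.0658) or among genes at 50 FPKM or more (0.103).

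Other energy genes gave no list call in the main test. NADH dehydrogenase I had 13 of 14 members lower, with all 14 under 20 FPKM (camera adjusted p = 0.127). After centring on the median this list passed as lower (adjusted p = 0.0138, and adjusted p = 0.236 with an estimated correlation). Its gene nuoG went from 17.2 ± 3.63 to 2.53 ± 0.555 FPKM, and nuoN, MSMEG_2054 and MSMEG_2059 had log2 fold changes of -1.63, -1.82 and -1.64. Of 22 hydrogenase genes 7 rose and 7 fell, with 4 members under 20 FPKM (camera adjusted p = 0.189, direction higher, with a median of 0.03 and a mean of -0.26). MSMEG_3928, MSMEG_3929, MSMEG_3930 and MSMEG_3931 fell, with log2 fold changes of -1.23, -1.14, -1.10 and -0.73.

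Ribosomal protein genes of the main operons fell in 25 of 31 cases and rose in 3. The largest falls were rplJ, from 5426 ± 53.7 to 2430 ± 34.8 FPKM, and rplL, from 4720 ± 50.6 to 2317 ± 12.9. For rpsD and rpsH the log2 fold changes were -0.45 and -0.37. The ribosomal list median was -0.21 (camera adjusted p = 0.0192, and adjusted p = 0.624 with an estimated correlation). After centring on the median the list and rpsH had the opposite direction, with a list median of 0.16, and without the intensity trend the list did not pass (0.285). The list for alternative ribosomal proteins made under zinc shortage held 5 ribosomal protein genes and MSMEG_6069, a CobW/P47K domain protein gene beside them. All 6 members were lower and under 20 FPKM, and the list did not pass (camera adjusted p = 0.14). Centring on the median brought it past the threshold (adjusted p = 0.0307, and adjusted p = 0.236 with an estimated correlation). MSMEG_6069 went from 17.0 ± 2.10 to 2.66 ± 0.665 FPKM. MSMEG_6065, MSMEG_6066 and MSMEG_6067 had log2 fold changes of -2.42, -2.02 and -2.22.

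Genes of mycolic acid synthesis, which builds the long lipids of the mycobacterial cell wall, fell in 10 of 12 cases and rose in 0. MSMEG_4327, a 3-oxoacyl-ACP synthase, fell from 6151 ± 118 to 3382 ± 11.1 FPKM. MSMEG_4328 fell from 2288 ± 31.0 to 1438 ± 14.9 FPKM, MSMEG_4329 from 2114 ± 26.4 to 1192 ± 12.2, and the polyketide synthase MSMEG_6392 fell by 0.81 on the log2 scale. The mycolic acid median was -0.44 (camera adjusted p = 0.00907, and adjusted p = 0.505 with an estimated correlation). Its call ended after centring on the median (adjusted p = 0.968, with a median of -0.06) and without the intensity trend (0.107). Acyl-CoA dehydrogenases, enzymes of fatty acid breakdown, fell in 78 of 86 cases and rose in 3, with 40 members under 20 FPKM. Their median was -1.17 (camera adjusted p = 3.6e-05, and adjusted p = 0.567 with an estimated correlation). The median was smaller after quantile normalization (-0.32), with a pseudocount of 10 alone (-0.71), and with that pseudocount and subtraction of the 25th percentile together (-0.09). It was also smaller among genes at 50 FPKM or more (-0.56) and 100 or more (-0.42). Strong members included MSMEG_2080 (1389 ± 18.3 to 792 ± 2.91 FPKM), MSMEG_2081 (1426 ± 27.9 to 886 ± 5.94 FPKM) and MSMEG_0531 (log2 fold change -1.16). MSMEG_5720 (log2 fold change -0.56) is a 3-hydroxyacyl-CoA dehydrogenase that the name search also took in. At 50 FPKM or more, 14 of the 17 members fell and 2 rose (camera adjusted p = 1.8e-04, and adjusted p = 0.155 with an estimated correlation).

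Lipid transport genes of the MCE and YrbE family fell in 34 of 40 cases and rose in 1 (35 and 1 adjusted over the list alone), with 23 members under 20 FPKM. MSMEG_4785 fell from 9.0 ± 1.21 to 1.53 ± 0.147 FPKM and MSMEG_4787 fell by 2.11 on the log2 scale. The family passed (camera adjusted p = 0.0395, and adjusted p = 0.674 with an estimated correlation). Its call ended after quantile normalization (0.432), centring (0.0572), rescaling to TPM (0.0512) and subtraction of the 25th percentile (0.433). It also ended among genes at 10 FPKM or more (0.0766) and 50 or more (0.129). Leaving out knockout library 2 (0.0605), knockout library 3 (0.0550) or wild-type library 1 (0.0522) had the same effect. All 8 mce1 genes fell, with a median wild-type level of 46.0 FPKM, and the mce1 list did not pass (camera adjusted p = 0.14). Subtraction of the 25th percentile brought it past the threshold (0.0423, and 0.214 with an estimated correlation). MSMEG_0139 fell from 58.8 ± 5.85 to 31.7 ± 1.52 FPKM, and MSMEG_0136, MSMEG_0137 and MSMEG_0138 had log2 fold changes of -0.79, -0.60 and -0.71. Of 8 mce4 genes 5 fell and 0 rose (camera adjusted p = 0.909). MSMEG_5895, MSMEG_5896, MSMEG_5897 and MSMEG_5902 stood at -0.29, -0.26, -0.32 and -0.35, all with the opposite sign after centring.

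In the glycopeptidolipid locus, which makes surface lipids, 4 of 32 genes rose and 21 fell, with 2 members under 20 FPKM (camera adjusted p = 0.716). The locus passed as lower after quantile normalization (0.00919) and subtraction of the 25th percentile (0.0423), with adjusted p of 0.296 and 0.459 there by an estimated correlation. MSMEG_0394 rose from 947 ± 48.0 to 1909 ± 23.5 FPKM and MSMEG_0395 from 89.4 ± 2.05 to 175 ± 10.8. MSMEG_0390 and MSMEG_0381 fell, with log2 fold changes of -0.82 and -0.62. Acyl-CoA synthetases had 8 of 45 members higher and 30 lower, with 18 under 20 FPKM (camera adjusted p = 0.446). Among them were MSMEG_3465 (0.78), MSMEG_5435 (-0.57), MSMEG_0599 (-1.16) and MSMEG_6393 (-0.36, opposite after centring). Enoyl-CoA hydratases had 3 of 43 higher and 36 lower, with 24 under 20 FPKM (camera adjusted p = 0.0621), and the list passed as lower after centring (0.0143, and 0.236 with an estimated correlation). Examples were MSMEG_5639 (0.40), MSMEG_5185 (-1.33), MSMEG_4775 (-2.53) and MSMEG_0259 (-1.56). Of 7 glyoxylate shunt and methylcitrate genes 1 rose and 4 fell, with 4 under 20 FPKM (camera adjusted p = 0.826). MSMEG_0255 and MSMEG_6645 stood at -0.62 and -1.32. For prpB (-1.28) and MSMEG_6647 (-0.78) the sign was the opposite after quantile normalization.

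Chaperone genes were mixed: 6 of 11 rose and 3 fell (7 and 3 adjusted over the list alone). The co-chaperonin gene groES rose from 3195 ± 147 to 5282 ± 105 FPKM and the heat shock repressor gene hrcA by 0.75 on the log2 scale. The genes dnaK and MSMEG_0711 (DnaJ) had log2 fold changes of -0.31 and -0.22, both with the opposite sign after centring. As a list they passed as higher (camera adjusted p = 0.0155, and adjusted p = 0.465 with an estimated correlation). The call ended after quantile normalization (0.459), rescaling to TPM (0.0814, with a median of -0.02) and subtraction of the 25th percentile (0.363), and among genes at 10 FPKM or more (0.0653) and 50 or more (0.596). Among sigma and anti-sigma factors, 7 of 32 rose and 18 fell, with 13 under 20 FPKM. The list did not pass (camera adjusted p = 0.528, direction higher, with a median of -0.43 and a mean of -0.56). The gene for the envelope stress sigma factor SigE (MSMEG_5072) rose from 1682 ± 19.4 to 2717 ± 25.7 FPKM and that for SigB (MSMEG_2752) from 3740 ± 105 to 4915 ± 11.6. MSMEG_6127 and MSMEG_1914 rose by 0.44 and 0.40. Antioxidant genes had 6 of 32 higher and 22 lower, with 8 under 20 FPKM (camera adjusted p = 0.991, direction higher, with a median of -0.32 and a mean of -0.39). The thioredoxins MSMEG_3138 and MSMEG_6934 and the thioredoxin reductase gene trxB rose by 0.48, 0.38 and 0.42. The catalase-peroxidase MSMEG_6384 fell by 0.73.

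The dormancy genes associated with the regulator DosR had 12 of 16 lower and 2 higher (12 and 3 adjusted over the list alone). The list did not pass in the main test (camera adjusted p = 0.14). It passed as lower after quantile normalization (3.3e-04), TPM rescaling (0.0442) and subtraction of the 25th percentile (0.00308), and among genes at 50 FPKM or more (0.00752) and 100 or more (0.0105). With an estimated correlation these settings gave adjusted p from 0.0963 to 0.471. MSMEG_3945 (universal stress protein) fell from 2065 ± 54.9 to 1209 ± 16 FPKM, and MSMEG_3948, MSMEG_3942 and MSMEG_5241 had log2 fold changes of -0.91, -0.41 and -0.53. The genes associated with SigF had 9 of 12 lower and 2 higher (camera adjusted p = 0.14). That list passed as lower after quantile normalization (3.3e-04) and subtraction of the 25th percentile (5.6e-04), and among genes at 50 FPKM or more (0.00795) and 100 or more (0.0306). Its adjusted p there with an estimated correlation ran from 0.0963 to 0.231. The carotenoid genes MSMEG_2346 (phytoene synthase), MSMEG_2344 and MSMEG_2343 fell, with log2 fold changes of -0.79, -1.12 and -1.19, and MSMEG_2345 beside them fell from 269 ± 4.20 to 134 ± 0.453 FPKM. DNA damage genes had 6 of 10 lower and 1 higher, with 1 under 20 FPKM (camera adjusted p = 0.580). MSMEG_1622 and MSMEG_1620 stood at -2.12 and -1.86. For recA and recX the log2 fold changes were both -0.31, with the opposite sign after centring.

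Among genes for nutrient uptake, nitrogen limitation genes fell in 11 of 12 cases, with 4 under 20 FPKM. Glutamine synthetase (MSMEG_4290) fell from 3329 ± 62.5 to 2156 ± 27.0 FPKM and the ammonium transporter MSMEG_2425 from 223 ± 3.67 to 138 ± 1.70. MSMEG_2187 and atzF had log2 fold changes of -2.16 and -1.16. The nitrogen list passed (camera adjusted p = 0.0455, and adjusted p = 0.465 with an estimated correlation). It did not pass after centring (0.207), without the intensity trend (0.0651), with a replicate block (0.0505) or among genes at 10 FPKM or more (0.0653). Nor did it pass without knockout library 3 (0.0612) or wild-type library 1 (0.0526). Phosphate transport genes rose in 6 of 13 cases and fell in 4 (5 and 4 adjusted over the list alone), with 3 under 20 FPKM. The regulator gene MSMEG_5776 (PhoU) rose from 459 ± 16 to 681 ± 19.9 FPKM and pstB by 0.32 on the log2 scale. MSMEG_0648 and MSMEG_0646 stood at -2.55 and -1.70. That list passed as higher (camera adjusted p = 0.0422, and adjusted p = 0.465 with an estimated correlation), with a median of 0.19 and a mean of -0.29. Other settings gave medians from 0.11 after TPM rescaling to 0.57 after centring. It did not pass after quantile normalization (0.0667), centring (0.206) or subtraction of the 25th percentile (0.0648), or among genes at 10 FPKM or more (0.0735) and 50 or more (0.0778). The call also ended without knockout library 1 (0.0550), knockout library 2 (0.0605), wild-type library 1 (0.0522) or wild-type library 3 (0.0570). ABC transporters fell in 170 of 215 cases and rose in 19 (172 and 19 adjusted over the list alone), with 102 under 20 FPKM. As a list they passed (camera adjusted p = 0.00622, and adjusted p = 0.633 with an estimated correlation), and not after quantile normalization (0.13), subtraction of the 25th percentile (0.0648) or among genes at 50 FPKM or more (0.0625). MSMEG_6309, MSMEG_1366, and the sugar transporter genes MSMEG_5573 and MSMEG_5572 had log2 fold changes of -1.04, -0.78, -2.33 and -2.27.

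The remaining lists did not pass in the main test. TetR family regulators, for which the name search also took in tetrahydrofolate and similar products such as MSMEG_1647 (0.42), had 24 of 116 higher and 62 lower. The list held 40 genes under 20 FPKM (camera adjusted p = 0.448, direction higher, with a median of -0.38 and a mean of -0.51). Among its 25 genes at 50 FPKM or more, 16 rose and 2 fell, and the list passed as higher (0.0357, and 0.233 with an estimated correlation). It also passed as higher after quantile normalization (0.0124, with a median of 0.19) and subtraction of the 25th percentile (0.0386, with a median of 0.20). An estimated correlation gave 0.193 and 0.110 there. MSMEG_0916 rose by 0.62, and MSMEG_1355 and MSMEG_1509 fell, with log2 fold changes of -1.82 and -2.17. Cytochrome P450 genes had 3 of 34 higher and 28 lower, with 25 under 20 FPKM (camera adjusted p = 0.462). Among genes at 100 FPKM or more the list passed as higher, with a median of 0.93 (0.0259, and 0.231 with an estimated correlation). Those few genes were selected by level and include MSMEG_6478 of the ltmA locus. With 28 of the 34 members lower, this is not a rise of the family. Of its 5 genes at 50 FPKM or more 3 rose and 2 fell, and the list did not pass (camera adjusted p = 0.202). The risers were MSMEG_6478, MSMEG_0762 (199 ± 4.17 to 380 ± 10.3 FPKM) and MSMEG_6312 (88.9 ± 1.70 to 156 ± 7.52 FPKM). MSMEG_1775 fell by 0.77. Regulators of the MarR, Fur and SoxR families with Dps had 4 of 39 higher and 23 lower, with 9 under 20 FPKM (camera adjusted p = 0.917). That search also took in MSMEG_4662, recB and recD, at -1.26, -1.14 and -1.20, which are an aldolase and subunits of a DNA repair nuclease. MSMEG_6824, a MarR regulator, fell by 1.49.

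Transposases and integrases had 2 of 37 higher and 14 lower (1 and 12 adjusted over the list alone), with 34 under 20 FPKM. Their list did not pass (camera adjusted p = 0.699, direction higher, with a median of -0.35 and a mean of -0.51). After quantile normalization the list passed as higher, with a median of 0.95 (3.3e-04, and 0.245 with an estimated correlation). MSMEG_6023, MSMEG_6600, MSMEG_4157 and MSMEG_4154 stood at -2.17, -1.86, -1.67 and -1.58. The list named for tRNA and rRNA genes held mostly enzymes that modify these RNAs, with 2 of 9 higher, 5 lower and 1 under 20 FPKM. It did not pass (camera adjusted p = 0.862, direction higher, with a median of -0.29 and a mean of -0.37). The genes rimM, MSMEG_5774, mnmA and MSMEG_4502 stood at -0.48, -0.29 (opposite after centring), 0.49 and 0.39. Of the 2 genes of cyclic di-GMP turnover, too few for a list test, MSMEG_2774 (diguanylate cyclase) fell from 81.6 ± 5.48 to 69.1 ± 1.42 FPKM. Its log2 fold change was -0.24 (adjusted p = 0.0035), with the opposite sign after centring. MSMEG_2196 had a log2 fold change of -0.09 (adjusted p = 0.185).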

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

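The filters at 50 and 100 FPKM, the subtraction of the 25th percentile together with a pseudocount of 10, voom, the case-matched lists and other settings joined with an estimated correlation were chosen after the data were seen. Fits with count-based tools had been planned for a table of counts, and were not run on the FPKM table; voom on the recovered reads was added. The number of genes past the threshold ranged from 4058 to 5540 under other pseudocounts, filters up to 10 FPKM, normalizations, the fit without a trend and the replicate block, against 5397 in the main test, and from 5125 to 5396 with each library left out in turn; ltmA stayed lower and past the threshold in all of these, with log2 fold changes from -5.38 to -1.79. A 2-fold limit left 2071 genes (75 higher and 1996 lower), as its construction requires. Quantile normalization gave 1995 higher and 2078 lower, and centring on the median 2413 and 2669. Filters at 50 and 100 FPKM gave 2117 genes (999 lower) and 1501 genes (640 lower), with fewer genes tested. Subtracting the 25th percentile with a pseudocount of 10 gave 3298 genes, 2018 higher and 1280 lower, and a log2 fold change of -1.11 for ltmA; voom gave 5330 genes. The number of lists past the threshold, 15 in the main test, was 0 with an estimated correlation and 32 by fry, which tests another question, and ranged from 12 to 15 with each library left out. It was 10 after centring (7 of them among the 15), 15 after quantile normalization (10), 14 after TPM rescaling (13) and 16 after subtraction of the 25th percentile (11). Without a trend and at 10 FPKM or more it was 11, all among the 15, and at 50 and 100 FPKM or more it was 12 (9) and 11 (8). These scalings and filters together called 10 lists beyond the 15; with an estimated correlation joined to these scalings and to the filters at 50 and 100 FPKM, 0 lists passed. Case-matched searches left 14 lists, the MCE and YrbE list being lost (adjusted p = 0.0669), and 108 TetR and 26 MarR, Fur and SoxR members. Except for the settings whose construction shows it, the cause was not tested.

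Direction changed in these cases. After quantile normalization prpB stood at 0.29 and MSMEG_6647 at 0.74, the latter alone past the threshold in its new direction (adjusted p = 0.00756). After centring on the median rpsH stood at 0.0064, MSMEG_6393 at 0.0199, MSMEG_5902 at 0.0255, MSMEG_5897 at 0.0598, recA at 0.0651, MSMEG_4267 at 0.0680, dnaK at 0.0714, recX at 0.0729, MSMEG_5895 at 0.0853, MSMEG_5774 at 0.0874, MSMEG_5896 at 0.12, MSMEG_2774 at 0.14, MSMEG_4268 at 0.15 and MSMEG_0711 at 0.16. The list medians of the main ribosomal proteins and of bcc-aa3 oxidase moved to 0.16 and 0.11. After TPM rescaling the chaperone median moved from 0.07 to -0.02. List direction was followed for the 15 lists past the threshold, a choice made after the first tally; the cause was not tested. The replicate numbers do not pair the libraries: same-numbered libraries had correlations of deviations of 0.08, -0.00 and -0.13. With the replicate block 5378 genes and 14 lists passed. At these depths a gene of 1 kb is counted in steps of 0.0650 to 0.0938 FPKM, which limits values under about 1 FPKM.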

Other observations

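The tests of the ltmA locus, of the ESX lists and of neighbouring genes below were chosen after the results were seen, as were the genes named here; the tests of weakly expressed genes and of other splits were written before. The neighbouring-gene test was first set out with a prediction, which was dropped after its result was seen, and only its value is given.

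A block of 4 adjacent genes, MSMEG_1422 to MSMEG_1425 (bases 1523066 to 1526610), fell as a group. MSMEG_1423, a radical SAM protein gene, fell from 1215 ± 2.82 to 484 ± 4.62 FPKM (log2 fold change -1.33, SE 0.02), and MSMEG_1422, MSMEG_1424 and MSMEG_1425 had log2 fold changes of -1.12, -1.19 and -1.07. This block and the 7 ESX-3 genes from MSMEG_0619 to MSMEG_0626 were the 2 runs of at least 4 adjacent lower genes. Genes were ordered by start position, and each in a run was at least 2-fold lower at 50 FPKM or more. The ESX-3 run does not hold MSMEG_0625, which did not pass. At most 0 such runs were seen in 1000 shuffled gene orders (permutation p = 0.001, one-sided, the smallest they can give). Shuffling treats neighbours as independent, so genes on a shared transcript can give this value by themselves. MSMEG_2093, a non-coding RNA and the most abundant transcript, took 5.15%, 5.08% and 5.04% of reads in the knockout and 2.94%, 2.60% and 2.68% in the wild type. The ferritin family gene MSMEG_6422, for iron storage, rose from 5344 ± 36.8 to 7206 ± 36.6 FPKM (log2 fold change 0.43, limma adjusted p = 2.0e-10), and the gene of the iron-dependent repressor IdeR, MSMEG_2750, rose from 707 ± 47.4 to 907 ± 14.4 FPKM (log2 fold change 0.36).

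Weakly expressed genes were lower in the knockout, and equal depth did not remove this: with every library thinned to 10000000 reads, 4108 genes were lower, against 4138. FPKM is already scaled by the total of assigned reads. Thinning could therefore change this count little, and it is weak evidence against a difference in depth. An even background of reads over all genes in the wild-type libraries stays open: among 3006 genes at 2 to 32 FPKM in the knockout, the excess of wild-type library 2 over library 1 followed that of library 3 over the knockout, with a Spearman rho across genes of 0.441. That test decides nothing, although a high rho had been set as the sign of a background, because it shows an excess that repeats gene by gene, which an even background does not need and a shared biological state may also give. Genotype and plasmid insert stay open as causes and cannot be told apart, since 0 libraries carry an insert shared by both strains. A source such as genomic DNA was not tested here.

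Genes on both sides of ltmA were higher in the knockout. The tables argue against one continuous, evenly covered transcript from MSMEG_6480 to MSMEG_6476 as the cause of the rise of MSMEG_6478, which gained 5677 FPKM while MSMEG_6477, inside the same stretch, stood at 179 ± 15.7 in the knockout. For MSMEG_6480 (124 FPKM in the knockout) such a transcript reading out of the insertion stays open. The log2 fold change of -2.24 (SE 0.05) in MSMEG_6477 does not exclude a transcript of that level, since loss of the gene's own signal could hide one. MSMEG_6476 rose from 30.9 ± 5.66 to 276 ± 14.9 FPKM. An evenly covered transcript giving that whole rise would also show in MSMEG_6477, which stood at 179 ± 15.7. That is below the rise, but by a margin that uneven coverage could give, so these values do not decide. A transcript giving all or part of the rise of MSMEG_6476 stays open, as does an effect local to the chromosome region. At least 2-fold rises were seen in 8 of 20 tested genes within 10 genes of ltmA and in 67 of 6693 elsewhere (Fisher's exact p = 1.9e-11, two-sided), but these 8 genes are the ones that showed the pattern, so the value describes it and decides nothing. The inserted cassette and loss of LtmA at its own locus cannot be told apart, since every knockout library has both.

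ESX-3 and ESX-1 genes were lower in the knockout, and an even background of the size seen in weak genes is too small to account for them: the median excess in the wild type was 99.9 FPKM for ESX-3 and 59.7 for ESX-1, against 10.1 for genes at 4 to 8 FPKM in the knockout. A shared response to iron supply stays open for ESX-3, which serves iron uptake. The exochelin and mycobactin list lay at percentile 0 among lists matched on expression. The ATP synthase, mycolic acid and ESX-1 lists did too, so this value does not single out iron. Median levels of the iron list were 27.3 FPKM in the wild type and 11.4 in the knockout. Its excess was not set against that of weak genes as for the ESX lists. With the 25th percentile subtracted and a pseudocount of 10 its median was -0.58 (camera adjusted p = 1.9e-04, and adjusted p = 0.184 with an estimated correlation). ESX-1 was not tested against iron supply. Genotype and insert stay open here too.

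The 6 libraries can be split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. By limma, 1 of the 10 splits, the real one, gave 5397 genes past the threshold. The highest of the others gave 0, with at most 12 genes at an unadjusted p under 0.05. Every other split puts knockout and wild-type libraries in the same group, so their difference enters the spread within groups. A low number of genes there was fixed in advance and does not measure what chance gives. For lists, 1 of the 10 gave 15, and the highest of the others gave 11, reached by grouping knockout libraries 1 and 2 with wild-type library 2.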
